A study of Mus musculus with 12 samples.

How the data were processed

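RNA sequencing libraries of 12 samples labelled as monocytes from mouse meninges were used, 3 from each of 4 groups: unstressed mice, and mice given vehicle, psilocybin or MDMA after 18 days of restraint. Per the labels' protocols, cells were obtained with a magnetic monocyte isolation kit, RNA was extracted with the PicoPure kit and measured with Qubit, and libraries were made with a NEBNext kit from 5 ng of RNA. Groups and replicate numbers were taken from the sample titles. The deposited values of every library were whole-number counts of reads per gene, not normalized. Per the submitters' processing notes, fastp 0.23.2, FastQC 0.11.9, MultiQC 1.11, STAR 2.7.5c, featureCounts 2.0.1 and edgeR 3.42.4 were used with the mm10 build; their order and settings are not given in the sources used here. Per the file headers, the unstressed libraries were counted with featureCounts over exons grouped by gene in a RefSeq annotation of mm10, with no strand or paired-end option in the recorded command. The stressed libraries carried versioned Ensembl gene identifiers, and their annotation release and counting command are not given in the sources used here. A table of the whole series held 9 columns identical to the files of the stressed libraries and 3 columns of no sample used here, which were not analysed.

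The annotations were joined before any comparison. Of 55401 Ensembl identifiers in the stressed files, 55141 had a symbol in GENCODE vM21 for GRCm38, the assembly also called mm10, and the unstressed files listed 35976 RefSeq genes. In all, 27570 genes were joined, 26660 by symbol and overlapping locus and 910 by position, as each other's best exon overlap with a Jaccard index of at least 0.5. The joined genes held 94.8% to 99.09% of each library's counts. Of these genes, 7395 had nearly the same exons in both annotations (Jaccard index of at least 0.9 and length not shared with other genes within 1.1 times). Gene positions come from GENCODE vM21 and are counted from 1.

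Tests were chosen before the data were examined. Counts were scaled by the trimmed mean of M values (TMM), genes were filtered with filterByExpr, and edgeR 4.0.16 quasi-likelihood tests were run in R 4.3.3 over all 12 libraries without a replicate block. Same-numbered libraries of the vehicle and psilocybin groups deviated together from their group means (correlations across genes of 0.112, 0.213 and 0.115), so the replicate number was taken to pair them. This was read from the data after the fits had been seen, and the labels do not say what the number marks. The 6 comparisons of group pairs and 1 test of any difference among the 4 groups used Benjamini-Hochberg adjustment at 0.05. Fold changes are log2 values with standard errors derived from the test statistic, and CPM beside them use TMM-scaled library sizes; marker sums, single-library levels, the most abundant genes, Htr2c and Tph1 use unscaled library totals. Adjusted p-values without another name come from edgeR. A gene at 0 in all libraries of a group has its fold change given as a bound, from a floor of 3 counts over that group. The other group then enters with its pooled counts per scaled library size, which can differ from its mean CPM. For 1 to 3 counts over a group, the ratio of pooled counts per scaled library size is given with an exact (Clopper-Pearson) 95% counting interval.

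The genes named follow a rule fixed before the data were examined. In each of the 3 comparisons with vehicle or of vehicle with unstressed and in psilocybin against MDMA, these were up to 10 higher and 10 lower genes with the largest change among those past the threshold. They also needed a mean of at least 5 CPM, no overlap between the groups and a symbol that is not a predicted gene or clone. Added were up to 4 members with the smallest p of each list with members past the threshold, the 5 genes with the smallest p where under 5 passed, and 14 genes followed in every comparison (Ly6c2, Ccr2, Cx3cr1, Nr4a1, Il1b, Tnf, Fkbp5, Tsc22d3, Htr2a, Htr2b, Htr7, S100a8, Mrc1 and H2-Ab1). Comparisons of the drug groups with unstressed mice name no other gene by this rule.

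Gene lists were fixed in advance: 28 lists of cell-type markers and pathways, 13 of them for cell types, tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01 and at least 5 measured members. The same lists were tested with the correlation estimated from the residuals and with fry, and members were also counted with adjustment over the list alone. After seeing the data, 5 lists were added to describe the libraries: choroid plexus epithelium, pineal gland, leukocyte, osteoblast, and the neural and glial list without Ttr. Marker sums per library were compared as log2(CPM + 1) by two-sided exact permutation tests, whose smallest possible p for 3 against 3 is 0.1. Correlations over 12 libraries used 100000 permutations.

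The alternatives were DESeq2's size factors in edgeR, no filter, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma voom with quality weights, only the libraries compared, the replicate number as a block, each library left out in turn, thinning to the smallest library, and leaving out mitochondrial, haemoglobin and immunoglobulin genes. After seeing the data, 4 were added: only genes with nearly the same exons, only the 9 stressed libraries with all Ensembl genes, leaving out vehicle libraries 1 and 3 together, and only the libraries compared with only genes of nearly the same exons.

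The scripts were tested on simulated data for psilocybin against vehicle with 13942 genes, of which 200 were changed. The share of changed genes recovered was 0% at 2-fold, 2% at 4-fold, 28% at 16-fold and 66% at 64-fold, with 1 false call; a proliferation list raised 4-fold was called (camera adjusted p = 3.06e-13) and no other list was. These data gave all groups the same spread. In 20 further simulations of unchanged groups the vehicle libraries kept the larger spread estimated from them alone, and edgeR then called a mean of 504 genes lower in vehicle than in unstressed libraries. Total counts ran from 807725 to 5136953 per library, so that a count of 0 in the smallest library allows up to 3.8 CPM. Identity of the libraries with the labelled sex was checked with Y-linked genes, which were present in all libraries, and with Xist, which reached at most 4.79 CPM. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the join, permutation tests and figures.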

Results

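Bulk RNA sequencing was available for 12 libraries labelled as monocytes, the circulating precursors of many tissue macrophages, taken from the meninges, the membranes that cover the brain. The mice were male C57BL/6J animals in 4 groups with 3 libraries each. One group was not stressed, and the remaining groups went through restraint stress lasting 18 days and then received vehicle, psilocybin or MDMA 24 hours before the tissue was collected. Psilocybin is the precursor of psilocin, an agonist of serotonin receptors, and MDMA is an amphetamine derivative that releases serotonin and other monoamines. The doses are not given in the sources used here. The unstressed libraries held 2949163, 4008849 and 4504400 gene counts in replicates 1, 2 and 3. The vehicle libraries held 3623830, 807725 and 1954222, the psilocybin libraries 3378226, 2601848 and 4079069, and the MDMA libraries 3567094, 2859534 and 5136953. Among the 27570 genes found in both kinds of file, 13942 passed the filter on low counts and were tested. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these samples, part of which may be technical. The sequenced reads carried no molecular identifiers, so counting intervals and lower bounds cover counting error only.

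The libraries held abundant transcripts of several cell types besides monocytes. The highest mean levels over all libraries, as counts scaled to library size (CPM), belonged to Enpp2 (30900 CPM), which encodes autotaxin, to mt-Cytb (25900 CPM) of the mitochondrial genome, and to Ttr (21600 CPM), which encodes the transthyretin made by choroid plexus epithelium. The order differed between libraries: mt-Cytb came first in all 3 unstressed libraries and in vehicle library 3, and Ttr ran from 4210 to 5700 CPM in unstressed and from 32000 to 61000 CPM in psilocybin libraries. Summed choroid plexus markers came mostly from Enpp2 and Ttr, with 55100 and 61000 of 123300 CPM in psilocybin library 1. The sums reached 32600 ± 14300 CPM (SD, n = 3) in the unstressed group, 71700 ± 59600 in the vehicle group, 87400 ± 31200 in the psilocybin group and 34800 ± 11500 in the MDMA group. Fibroblast markers summed to 6880 ± 2090, 4810 ± 2630, 5390 ± 1950 and 12500 ± 3220 CPM in the same order, and endothelial and mural markers to 5110 ± 1440, 4520 ± 1380, 3790 ± 1140 and 4380 ± 337. Classical monocyte markers summed to 1120 ± 109, 918 ± 588, 689 ± 432 and 1790 ± 449 CPM, and border macrophage markers to 1550 ± 462, 2370 ± 453, 2250 ± 379 and 2210 ± 1070. Neutrophil markers stood at 54 ± 18.4, 158 ± 67.1, 482 ± 561 and 1930 ± 1150 CPM. Microglial markers stood at 1000 ± 315, 855 ± 359, 1350 ± 598 and 1970 ± 367, and those of non-classical monocytes at 1190 ± 322, 1070 ± 322, 1020 ± 113 and 963 ± 280. Much of the non-classical sum came from Nr4a1, which is also in the immediate early list. Cx3cr1, another marker of that list, had 102, 1, 58 and 285 counts in the same order. In vehicle library 1 the classical monocyte sum was 451.4 CPM, although its members Ly6c2 and Ccr2 stood at 0 and 0.283 CPM. A marker sum can thus be carried by some of its members and does not by itself measure the content of a cell type.

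The vehicle libraries held fewer genes than the others. Genes with at least 1 count numbered 11110 ± 2080 (SD, n = 3) in the vehicle group, 15870 ± 1600 in the unstressed group, 17190 ± 467 in the psilocybin group and 17020 ± 1460 in the MDMA group. All vehicle libraries lay below all libraries of each other group (two-sided exact permutation p = 0.1 for each, the smallest that 3 libraries against 3 can give). With every library thinned to the smallest total, the values were 10330 ± 2760, 14330 ± 1000, 15110 ± 236 and 14880 ± 1050, with exact permutation p = 0.2 for vehicle against unstressed and p = 0.1 against each drug group. Of 4779 abundant genes, vehicle libraries 1, 2 and 3 had no count for 196, 14 and 268, while no library of another group lacked more than 7. The Pearson correlation of log2 CPM between libraries of a group ran across genes, which are not independent replicates, from 0.476 to 0.614 in the vehicle group. The corresponding ranges were 0.824 to 0.856 in the unstressed, 0.901 to 0.951 in the psilocybin and 0.8 to 0.93 in the MDMA group.

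**Figure D1:**
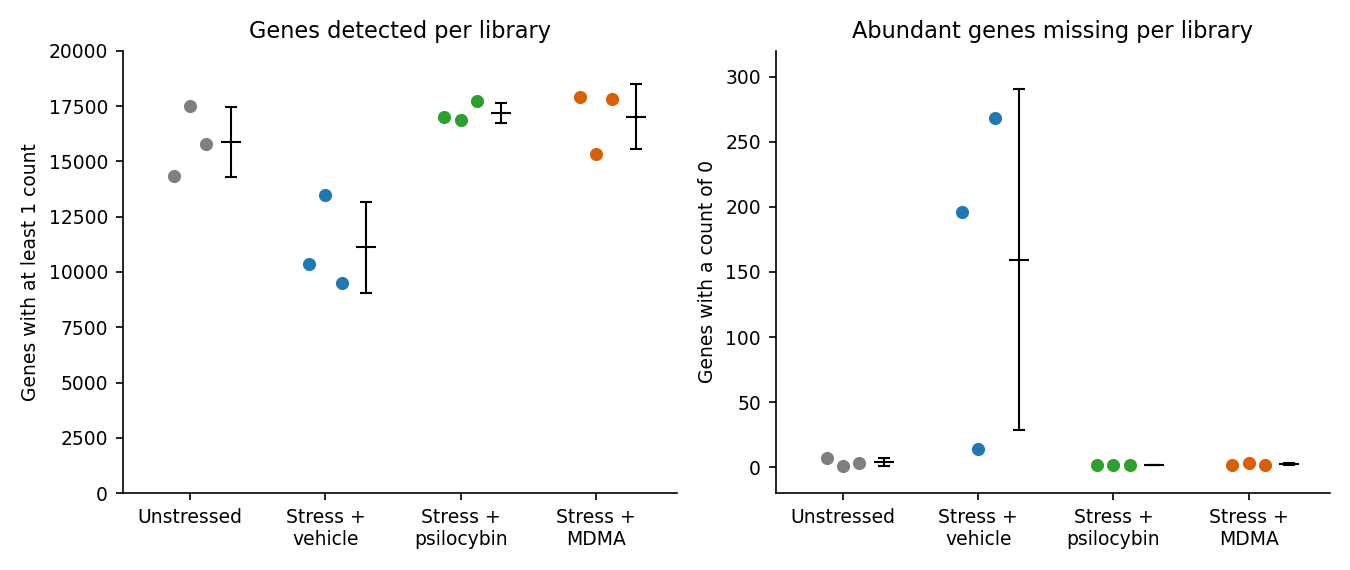
Genes with at least 1 count (left) and genes among 4779 abundant ones with a count of 0 (right) in each of the 12 libraries; points are libraries, and the bars beside them give the group mean and SD. Vehicle libraries 1 and 3 lacked 196 and 268 abundant genes, against at most 7 in any library outside the vehicle group.

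**Figure D2:**
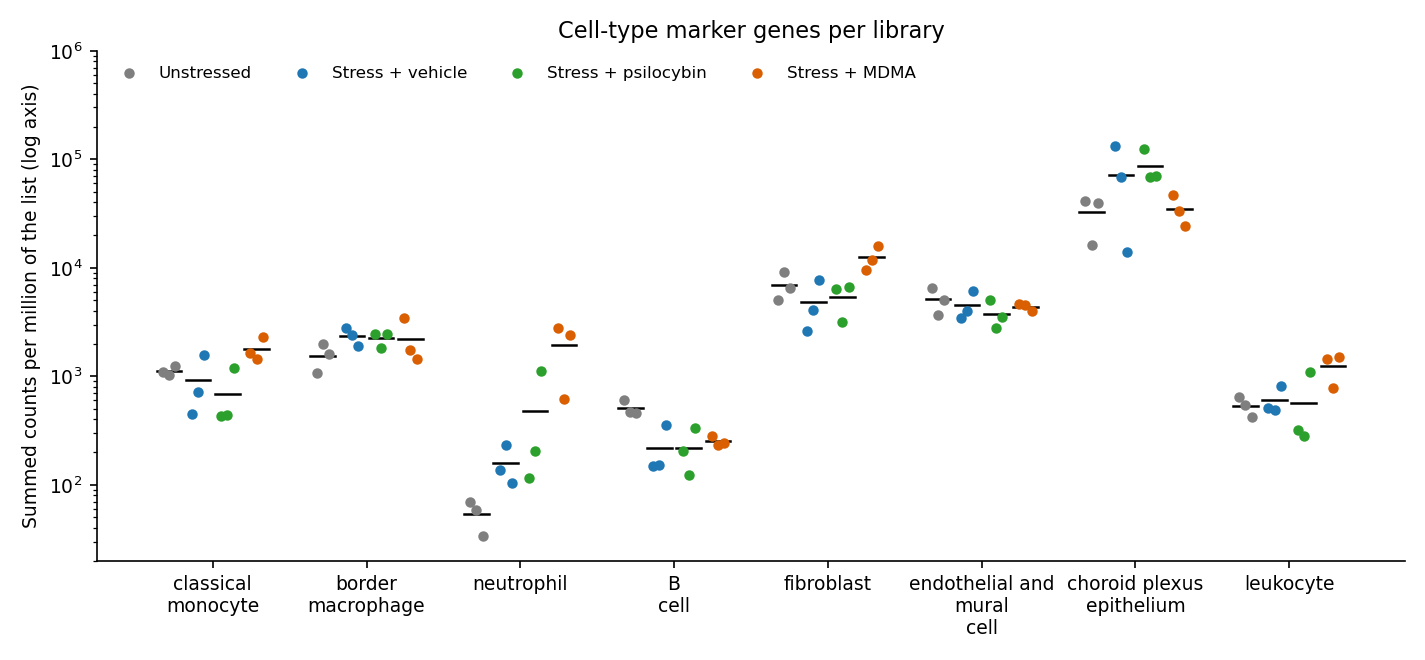
Summed CPM of 8 lists of cell-type marker genes in each library on a log axis; points are libraries and horizontal bars are group means of 3. Choroid plexus markers were the highest in every group (means of 32600 to 87400 CPM), and the neutrophil mean ran from 54 CPM in unstressed to 1930 CPM in MDMA libraries.

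The comparison of stressed, vehicle-treated mice with unstressed mice addressed how these libraries of mixed cell types differed after chronic stress. In the vehicle libraries, transcripts of Slc30a4, which encodes a zinc transporter, fell from 92.4 ± 22.1 CPM (SD, n = 3) to 0 in all 3 libraries, at least 170-fold lower (adjusted p = 0.00377 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Igf2, a growth factor gene of the leptomeninges, fell by 4.63 ± 0.79 (SE) on the log2 scale, from 248 ± 22.4 to 9.74 ± 8.64 CPM (edgeR Benjamini-Hochberg adjusted p = 0.0199). Itga6, an integrin subunit used in cell adhesion, fell by 3.76 ± 0.75 on the log2 scale, from 108 ± 31.9 to 7.76 ± 3.22 CPM (adjusted p = 0.0314). The stress-response transcription factor Atf3 rose by 1.83 ± 0.43 on the log2 scale, from 88.2 ± 23 to 314 ± 72.2 CPM (adjusted p = 0.041). The lactate dehydrogenase gene Ldha rose by 1.58 ± 0.40, from 133 ± 36.8 to 397 ± 128 CPM (adjusted p = 0.0491). In all, 477 of 13942 genes passed the test, 31 of them higher and 446 lower in the vehicle group. In 20 simulations of unchanged groups whose vehicle libraries kept their own spread, a mean of 504 genes passed as lower (highest 582), so that this spread alone gave as many.

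The genes with the largest changes under the rule fixed in advance mostly differed between the annotations. The unstressed libraries had been counted with another annotation than the stressed libraries. Of these 20 genes, 19 had over 2 times more exonic bases of their own in the annotation of the group with the higher counts. Sept2 (1510 ± 700 CPM in unstressed libraries, SD, n = 3), Zc3h11a (257 CPM), Nnt (78.2 CPM) and Myl12b (68.8 CPM) had 0 counts in all stressed libraries. They have 0 exonic bases of their own in the Ensembl-type annotation (GENCODE, GRCm38), against 3598, 4877, 3645 and 939 in RefSeq, so they could not be counted there and no decrease can be read. Ormdl2 (21.5 CPM in vehicle) has 0 such bases in RefSeq and could not be counted in unstressed libraries. In all, 8 of the 477 genes that passed could not be counted on one side. Ilk (118 ± 10.9 CPM), Cpne1, Pagr1a (94.9 CPM), Nrarp (74.5 CPM) and Chtf8 (65.9 CPM) had no count in any vehicle library, with 283, 718, 18, 531 and 250 bases of their own against 1808, 3291, 1412, 2582 and 3155. Higher in vehicle were Mia2 (220 ± 157 CPM against 0), with 11239 bases against 1628, and Bace1, the beta-secretase gene (log2 difference of 5.1 ± 0.81 SE, edgeR adjusted p = 0.015), with 4287 against 1269. Snrpn (6.92 ± 1.32), Ado (6.63 ± 1.16), Scamp3 (4.78 ± 0.80), Zfp652 (4.52 ± 0.89), Mir99ahg (4.47 ± 0.97) and Rab10os (3.81 ± 0.90) also passed the test. Tmem102 had 61 counts in the vehicle and 1 in the unstressed libraries, a ratio of 126 with a 95% counting interval of 21.9 to 5080, and 1933 bases of its own against 74. Igf2 had 2029 against 4890 bases, and Ldha 3310 against 1809, so part of their differences may come from the counting. Of the 20 genes in these groups of largest changes, only Slc30a4 had nearly the same exons in both annotations. Among the members of lists, Atf3 and Casp1 did. Antisense and overlapping genes such as Rab10os are uncertain, because no strand setting is stated for the counting. Slc30a4 (ENSMUSG00000005802) lies on chromosome 2, 122681233 to 122702663, on the minus strand in GRCm38 (mm10). Itga6 (ENSMUSG00000027111) lies on chromosome 2, 71745616 to 71858416, and Igf2 (ENSMUSG00000048583) on chromosome 7, 142650766 to 142666816. Atf3 (ENSMUSG00000026628) lies on chromosome 1, 191170296 to 191218039, and Sept2 (ENSMUSG00000116048) on chromosome 1, 93478993 to 93509733. The counts cover the exons of each whole gene.

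By gene list, nuclear genes of oxidative phosphorylation were higher relative to other genes in the vehicle group, by 1.48 in mean log2 difference (24 of 25 positive, adjusted p = 2.23e-05 by camera). So were ribosomal protein genes, by 1.68 (32 of 35 positive, adjusted p = 1.03e-08). The heat shock (1.2, adjusted p = 0.0229), glycolysis and hypoxia (1.01, 0.0171), neutrophil (1.5, 0.0452) and immediate early lists (0.971, 0.0452) were also higher relative to the rest. None of these 6 calls held with the correlation between genes estimated from the residuals. Oxidative phosphorylation, ribosomal and neutrophil lists had adjusted p = 0.749 with an estimated correlation, against 0.468 for the heat shock and immediate early lists, and 0.663 for glycolysis. Of the 6 lists, 1, 4 and 4 passed without vehicle library 1, 2 or 3, then 6, 6 and 4 without unstressed library 1, 2 or 3, and 2 without both vehicle libraries 1 and 3. The median of the glycolysis list itself was -0.00345, opposite in sign to its difference from the rest. The median of all genes was -0.182 with the main scaling and 0.0022 with DESeq2's size factors. The list differences are measured from the mean of all other genes, not from this median. A list can therefore stand above the rest without being raised itself. In 11 of the 28 lists the median and the difference from the rest had opposite signs. Over all genes, single members passed in the fibroblast (Igf2), adhesion (Itga6), glycolysis (Ldha), immediate early (Atf3 and Egr3), class II (Ciita), inflammatory (Casp1) and interferon-stimulated (Zbp1) lists. The inflammasome protease gene Casp1 fell from 9.9 ± 6.47 CPM to 0 in all vehicle libraries, at least 19-fold lower (edgeR adjusted p = 0.0482, n = 3). Counts of the class II transactivator Ciita were 1 in vehicle and 133 in unstressed libraries (ratio of 64.1, 95% counting interval 11.3 to 2550). Those of Zbp1 were 1 and 200 (96.5, 17.1 to 3830), and those of the transcription factor Egr3 were 3 and 329 (52.9, 17.9 to 258). Adjusted over the list alone, 3 of 11 B cell genes, 3 of 18 adhesion genes, 4 of 25 proliferation genes, 2 of 18 inflammatory genes and 2 of 12 class II genes fell. Of the T and NK cell genes, 3 of 13 fell while 2 rose, and of the 22 interferon-stimulated genes 2 fell while 1 rose. In the border macrophage, mast cell and fibroblast lists 1 gene each fell, in the neutrophil and glycolysis lists 1 each rose, and in the immediate early list 1 fell and 1 rose. Beside these lists, B cell markers summed to 220 ± 120 CPM in the vehicle and 511 ± 82.1 CPM in the unstressed group (SD, n = 3, two-sided exact permutation p = 0.1, 0.6 after Benjamini-Hochberg adjustment).

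Of the genes followed in every comparison, none passed the test after stress. The chemokine receptor gene Ccr2, which marks classical monocytes, stood at 14.1 ± 13.5 CPM (SD, n = 3) in vehicle and 65.2 ± 14 CPM in unstressed libraries (log2 difference of -2.23 ± 1.04 SE, edgeR Benjamini-Hochberg adjusted p = 0.268). Nr4a1, a transcription factor of patrolling monocytes, stood at 649 ± 143 and 597 ± 177 CPM. The glucocorticoid-responsive genes Fkbp5 and Tsc22d3 stood at 62.2 ± 49.5 against 38 ± 4.56 CPM and at 989 ± 445 against 875 ± 122 CPM. Ly6c2 stood at 21 ± 20.3 against 4.24 ± 3.31 CPM, Il1b at 10.6 ± 12.9 against 7.88 ± 4.31, Mrc1 at 92.4 ± 156 against 34.5 ± 40.9 and H2-Ab1 at 266 ± 81 against 206 ± 85.9. The serotonin receptor gene Htr2a had 0 counts in the vehicle and 5 in the unstressed libraries, Htr2b had 1 and 39, and Cx3cr1 had 1 and 102. Htr7 and Tnf, which were not tested, had 0 against 25 and 27. The count of 477 genes depended on which libraries were kept. It was 268, 3665 and 982 without vehicle library 1, 2 or 3, and 9, 10 and 8 without unstressed library 1, 2 or 3. It was also 1746 with DESeq2, 1 with limma voom and 2 with only the 6 libraries compared. With only genes of nearly the same exons it was 37, and Slc30a4 kept its call, whereas Atf3 and Casp1 lost theirs. Of the genes tested, 20.8% had no overlap between the groups, where chance gives 10%. In vehicle libraries 3.565% of all genes lay higher and 17.24% lower, the direction that genes missing from them also give.

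The comparison of psilocybin with vehicle asked how the drug acted after chronic stress. Slc30a4 rose from 0 in all 3 vehicle libraries to 44 ± 4.61 CPM (SD, n = 3), at least 79.9-fold higher (edgeR Benjamini-Hochberg adjusted p = 0.0314). Ubap1, which encodes a subunit of the ESCRT-I complex for endosomal sorting, rose by 5.91 ± 0.83 (SE) on the log2 scale, from 1.97 ± 1.55 to 103 ± 1.04 CPM (adjusted p = 0.0314). Ubap1 (ENSMUSG00000028437) lies on chromosome 4, 41348996 to 41390525. These were the only genes of 13942 past the threshold with edgeR, while 2224 had an unadjusted p under 0.05. The simulations of unchanged groups gave a mean of 484 genes higher after psilocybin, many more than were called. They overstate this count and so cannot set the spread of the vehicle libraries apart as a source of the 2 calls. Both genes were also among the 446 lower in vehicle than in unstressed libraries. The genes next in order of p did not pass. The histone demethylase gene Kdm6a had 386 counts against 2 in vehicle, a ratio of 106 with a 95% counting interval of 29.3 to 882 (38.7 ± 1.65 CPM, edgeR adjusted p = 0.0517). The others were Klhl42 (25 CPM against 0, adjusted p = 0.0687) and Zfp979 (466 counts against 1, ratio 257, interval 45.9 to 10200, adjusted p = 0.0687).

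Immediate early genes were lower relative to the rest after psilocybin (-1.27, adjusted p = 0.00803 by camera, adjusted p = 0.197 with an estimated correlation). So were endothelial and mural genes (-1.07, adjusted p = 0.0317, adjusted p = 0.843 with an estimated correlation). Of these 2 lists, 0, 0 and 1 passed without vehicle library 1, 2 or 3, then 2, 1 and 2 without psilocybin library 1, 2 or 3, and 0 without both vehicle libraries 1 and 3. No member of either list passed the test, and summed endothelial and mural markers stood at 3790 ± 1140 against 4520 ± 1380 CPM (SD, n = 3). Adjusted over the list alone, 7 of 25 proliferation genes, 4 of 7 mast cell and basophil genes, 3 of 11 B cell genes, 3 of 18 inflammatory genes, 2 of 18 adhesion genes and 1 of 19 phagocytosis genes rose. Over all genes, none of them passed. By fry, which tests whether the genes of a list move one way, the dendritic cell, mast cell, inflammatory and proliferation lists had an adjusted p of 0.0323. In 15 of the 28 lists the median of the list and its difference from the rest had opposite signs, beside a median of all genes of 0.308 with the main scaling and 0.119 with DESeq2's size factors. Of the genes followed throughout, S100a8, a neutrophil calprotectin subunit, stood at 108 ± 131 CPM (SD, n = 3) after psilocybin and 11.2 ± 13.9 after vehicle (log2 difference of 3.34 ± 1.16 SE, edgeR adjusted p = 0.168). Ccr2 stood at 39 ± 28.2 against 14.1 ± 13.5 CPM, and Nr4a1 at 527 ± 85.2 against 649 ± 143. Fkbp5 stood at 55.5 ± 19.2 against 62.2 ± 49.5, Tsc22d3 at 683 ± 297 against 989 ± 445 and H2-Ab1 at 137 ± 89 against 266 ± 81. Htr2a, the receptor through which psilocin acts on neurons, had 24 counts over the psilocybin libraries and 0 over the vehicle libraries. At 2.46 ± 2.58 CPM it was at least 4.42-fold higher but did not pass (adjusted p = 0.263 by edgeR). Htr2b had 25 against 1 (ratio 13.8, 95% counting interval 2.26 to 566). Htr2c, a receptor gene abundant in choroid plexus, stood at 264 ± 86.5 CPM in psilocybin, 206 ± 114 in vehicle, 193 ± 114 in MDMA and 155 ± 75 in unstressed libraries.

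The 2 calls depended on which libraries were kept. With edgeR the count was 0, 3533 and 140 without vehicle library 1, 2 or 3, and 0 without any one of the psilocybin libraries. It was 1061 with DESeq2, 0 with limma voom and 0 with the 9 stressed libraries alone, where the edgeR adjusted p of Slc30a4 and Ubap1 was 0.12. With the replicate number as a block the count was also 0, and Slc30a4 and Ubap1 differed by 10.06 and 6.01 on the log2 scale (edgeR adjusted p = 0.148 for each). Of the genes tested, 23.8% had no overlap between the groups, where chance gives 10%. Of all genes, 21.08% lay higher and 2.711% lower after psilocybin, the direction that genes missing from vehicle libraries also give.

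The comparison of MDMA with vehicle asked the same of MDMA, and all 94 genes that passed were higher after the drug. The simulations of unchanged groups gave a mean of 497 higher genes (highest 559), so that the spread of the vehicle libraries alone gave more. As for psilocybin, they overstate the count, so how many of the 94 genes come from this spread stays open. Top2a, the DNA topoisomerase of dividing cells, rose from 1 count over the vehicle libraries to 898 over the MDMA libraries (67.8 ± 28.2 CPM, SD, n = 3, edgeR Benjamini-Hochberg adjusted p = 0.0465). The ratio was 408 with a 95% counting interval of 73.1 to 16100. Itga6 rose by 3.57 ± 0.75 (SE) on the log2 scale, from 7.76 ± 3.22 to 94.1 ± 76.8 CPM (adjusted p = 0.0497). Slc30a4 rose from 0 to 64 ± 41.9 CPM, at least 103-fold (adjusted p = 0.0191), and Pygl, the liver form of glycogen phosphorylase, from 0 to 53.6 CPM, at least 95.7-fold (adjusted p = 0.0465). Lilrb4a, an inhibitory receptor of myeloid cells, rose from 0 to 30.7 ± 1.07 CPM, at least 56.7-fold (adjusted p = 0.0465). The other genes named by the rule were also at 0 in all vehicle libraries. At least 88.5-fold higher was the monocarboxylate transporter gene Slc16a7 (65 ± 83.9 CPM), and at least 71.3-fold higher was Enpp1 (33.5 ± 22.7 CPM). The lower bounds were smaller for Cenpj (56.9-fold), Eya4 (55.8-fold, 39.9 ± 48 CPM), Fam234b (51.6-fold), the NADPH oxidase gene Nox4 (47.2-fold, 31.6 ± 30 CPM) and the cadherin gene Fat3 (46.1-fold). Top2a (ENSMUSG00000020914) lies on chromosome 11, 98992943 to 99024189, and Lilrb4a (ENSMUSG00000112148) on chromosome 10, 51490956 to 51496611. Of the genes tested, 2334 had an unadjusted p under 0.05 and 18.9% had no overlap between the groups (16.48% higher and 2.388% lower after MDMA).

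All 12 measured neutrophil genes were higher in MDMA than in vehicle libraries (mean 2.47 above other genes on the log2 scale, adjusted p = 0.000178 by camera, adjusted p = 0.608 with an estimated correlation). By fry, which sets a list against no change and not against other genes, the adjusted p was 0.00953. Of the 12 genes, 9 rose when adjusted over the list alone and 0 over all genes. Summed neutrophil markers were 1930 ± 1150 against 158 ± 67.1 CPM (SD, n = 3, log2 difference of 3.41, higher in all 3 libraries, two-sided exact permutation p = 0.1, 0.257 after Benjamini-Hochberg adjustment). Proliferation genes were higher as a list (22 of 25 positive, by 1.87, camera adjusted p = 1.25e-05, adjusted p = 0.455 with an estimated correlation), and against no change fry gave them an adjusted p of 0.00317. Adjusted over the list alone 11 of 25 rose, 1 of them (Top2a) over all genes. Oxidative phosphorylation genes were lower relative to the rest (-1.34, 3 of 25 positive, camera adjusted p = 0.000117, adjusted p = 0.648 with an estimated correlation). The immediate early list was lower relative to the rest (-1, camera adjusted p = 0.0455, adjusted p = 0.455 with an estimated correlation) while its own median was 0.123. Of these 4 lists, 2, 2 and 4 passed without vehicle library 1, 2 or 3, then 3, 4 and 3 without MDMA library 1, 2 or 3. Adjusted over the list alone, 5 of 11 erythroid, 4 of 7 mast cell and basophil, 4 of 18 adhesion and 3 of 9 microglial genes rose. So did 3 of 11 B cell, 3 of 18 inflammatory and 2 of 22 interferon-stimulated genes, with 1 gene each of the classical monocyte, immediate early and phagocytosis lists, and of all these only Itga6 passed over all genes. Marker sums of microglia, mast cells, fibroblasts, erythroid cells and dendritic cells were higher in every MDMA than in every vehicle library, by 1.29, 2.52, 1.48, 3.48 and 0.623 on the log2 scale (two-sided exact permutation p = 0.1, 0.257 after adjustment, n = 3). The mast cell and erythroid differences rested on 1 vehicle library each (SD of 2.66 and 3.05 in that group) and were 0.985 without vehicle library 1 and 1.76 without vehicle library 3. Osteoblast markers, a list chosen after seeing the data, stood at 5060 ± 3410 CPM in MDMA and 1110 ± 829 in vehicle libraries.

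Among the genes followed throughout, S100a8 stood at 207 ± 223 CPM (SD, n = 3) after MDMA and 11.2 ± 13.9 after vehicle (log2 difference of 4.27 ± 1.2 SE, edgeR Benjamini-Hochberg adjusted p = 0.0901). Fkbp5 stood at 168 ± 91.5 against 62.2 ± 49.5 CPM (1.45 ± 0.68, adjusted p = 0.302) and Ccr2 at 74.7 ± 31.8 against 14.1 ± 13.5 (2.43 ± 1.05, adjusted p = 0.249). Nr4a1 stood at 502 ± 137 against 649 ± 143 CPM, and Tsc22d3 at 1140 ± 107 against 989 ± 445. Ly6c2 stood at 33.2 ± 12.8 against 21 ± 20.3, Il1b at 21.1 ± 4.55 against 10.6 ± 12.9, Mrc1 at 57.9 ± 27.9 against 92.4 ± 156 and H2-Ab1 at 205 ± 44.6 against 266 ± 81. Cx3cr1 had 285 counts against 1 (ratio 130, 95% counting interval 23.1 to 5140, edgeR adjusted p = 0.113). Htr2a had 43 against 0 (at least 6.52-fold higher, adjusted p = 0.217) and Htr2b had 36 against 1 (ratio 16.4, interval 2.76 to 664). The count of 94 genes was 3, 3612 and 280 without vehicle library 1, 2 or 3 and 0 without any one of the MDMA libraries. It was 3 with DESeq2's size factors, 1336 with the DESeq2 test, 0 with limma voom, 0 with the 9 stressed libraries alone and 0 without both vehicle libraries 1 and 3.

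**Figure D3:**
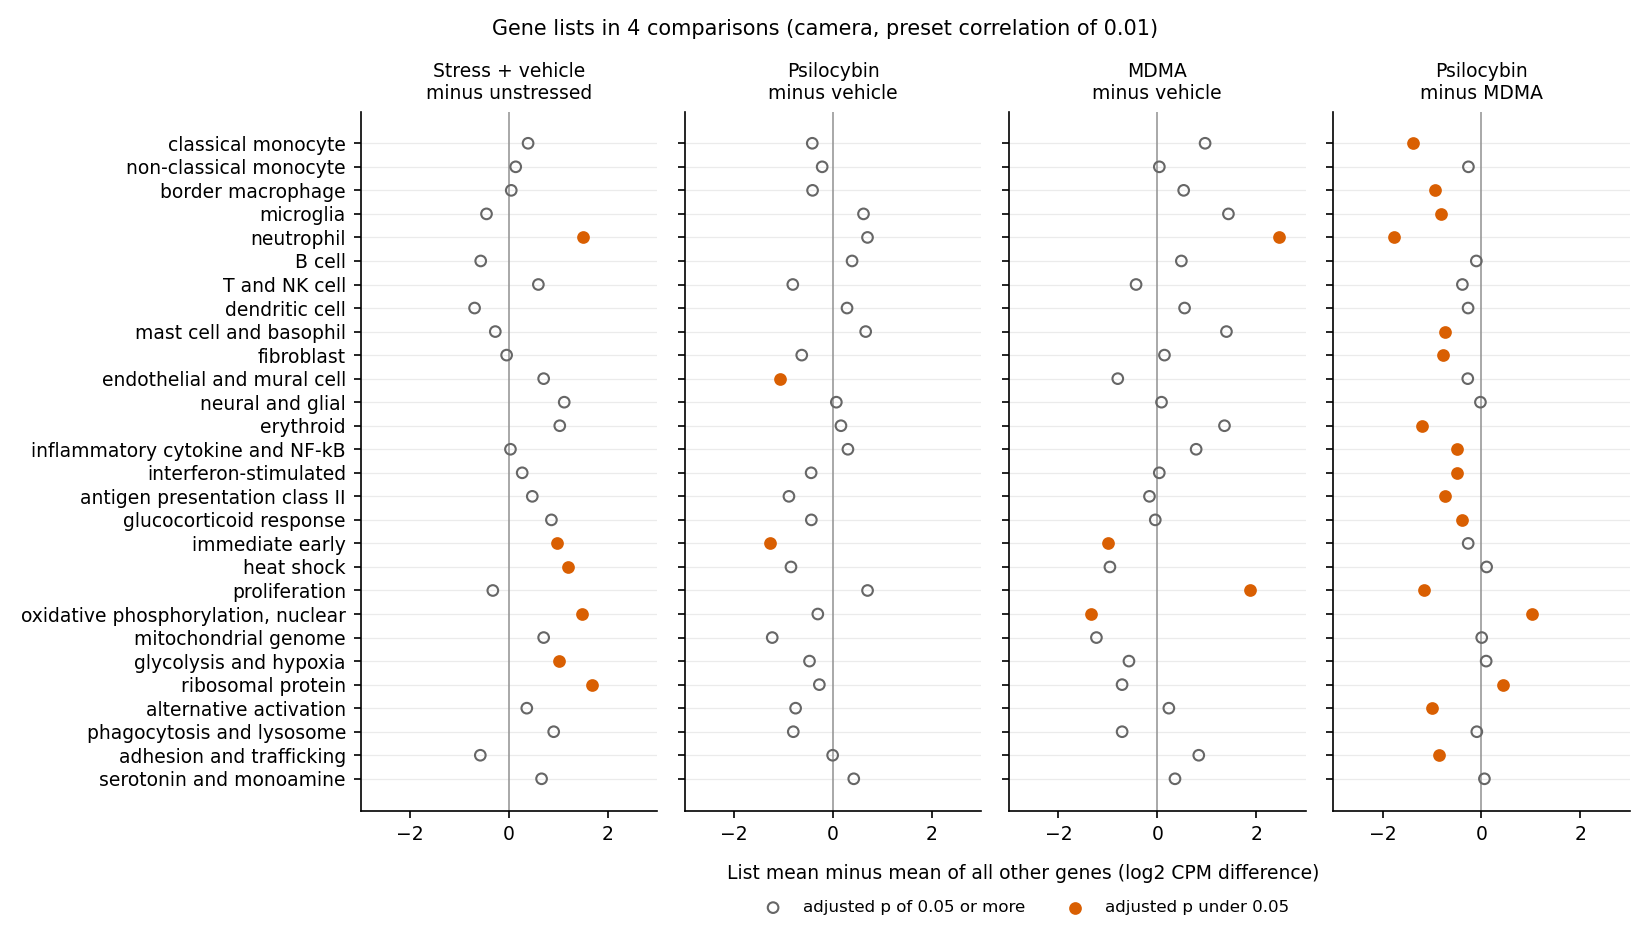
Mean log2 difference of each of the 28 gene lists minus that of all other tested genes in 4 comparisons, with filled points for lists past the threshold by camera at a preset correlation of 0.01. Psilocybin against MDMA had 16 filled points, from -1.77 for neutrophil genes to 1.03 for oxidative phosphorylation genes, none of which held with an estimated correlation.

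The direct comparison of psilocybin with MDMA asked whether the drugs differed. No single gene passed with edgeR's quasi-likelihood test, where 81 of 13942 genes had an unadjusted p under 0.05, nor with DESeq2 (165 unadjusted), while limma voom called 1 gene (1184 unadjusted). Cell-type and pathway lists differed in level. All 15 classical monocyte genes were lower after psilocybin than after MDMA (-1.39 relative to other genes on the log2 scale, adjusted p = 1.88e-09 by camera, adjusted p = 0.126 with an estimated correlation). So were 11 of 12 neutrophil genes (-1.77, 4.72e-11, adjusted p = 0.126 with an estimated correlation). All 25 nuclear genes of oxidative phosphorylation were higher after psilocybin (1.03, adjusted p = 4.49e-14 by camera, adjusted p = 0.208 with an estimated correlation). Among them were Cox4i1, a subunit of cytochrome c oxidase (755.9 against 398.8 CPM, log2 difference of 0.92 ± 0.70 SE) and Ndufa4 (518.8 against 188.8 CPM, 1.46 ± 0.84). Both were named outside the rule fixed in advance, and neither passed the test.

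Proliferation genes were lower after psilocybin than after MDMA (-1.17, 1 of 25 positive, camera adjusted p = 2.71e-12, adjusted p = 0.126 with an estimated correlation). Lower as well, each with its camera adjusted p and then the adjusted p with an estimated correlation, were adhesion genes (-0.848, 0 of 18 positive, 8.77e-07, 0.162) and alternative activation genes (-0.992, 0 of 11 positive, 7.4e-05, 0.208). Border macrophage (-0.949, 0.000141, 0.216), microglial (-0.827, 0.00445, 0.216) and erythroid genes (-1.2, 1.46e-05, 0.216) were lower, given in the same order. So were class II antigen presentation (-0.735, 9.24e-05, 0.216), fibroblast (-0.779, 2.03e-05, 0.208) and mast cell and basophil genes (-0.74, 0.0227, 0.219). Inflammatory (-0.486, 0.00659, 0.216), interferon-stimulated (-0.484, 0.00583, 0.219) and glucocorticoid response genes (-0.399, 0.00842, 0.216) were lower too. Ribosomal protein genes were higher after psilocybin (0.434, 32 of 35 positive, 3.17e-05, 0.398). No member of any of these lists passed over all genes or adjusted over the list alone with edgeR, and fry gave each list an adjusted p of 0.527. The number of these 16 lists past the threshold was 8 without psilocybin library 2, 11 without MDMA library 1 and 14 to 16 without any other library of the 2 groups. The remaining 12 lists did not pass by camera. Of the cell types these were B cell (adjusted p = 0.602), T and NK cell (0.128), dendritic cell (0.322), non-classical monocyte (0.332), endothelial and mural (0.115) and neural and glial genes (0.877). Of the pathways they were immediate early (0.128), heat shock (0.332), mitochondrial genome (0.936), glycolysis (0.233), phagocytosis and lysosome (0.825) and serotonin and monoamine genes (0.602).

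Summed markers gave a mixed picture. Border macrophage markers differed by 0.114 on the log2 scale, opposite to their list (exact permutation p = 0.8), and neutrophil markers by -2.42 (p = 0.2). Classical monocyte markers stood at 689 ± 432 CPM (SD, n = 3) after psilocybin and 1790 ± 449 after MDMA, and fibroblast markers at 5390 ± 1950 against 12500 ± 3220. In each case the libraries did not overlap (log2 differences of -1.52 and -1.25, n = 3, two-sided exact permutation p = 0.1, 0.3 after Benjamini-Hochberg adjustment). Choroid plexus markers, a list added after seeing the data, stood at 87400 ± 31200 against 34800 ± 11500 CPM (1.33, exact permutation p = 0.1). Osteoblast markers, also added, stood at 1070 ± 336 against 5060 ± 3410 (-2.08, exact permutation p = 0.1). The genes with the smallest p all had an edgeR adjusted p of 1. They included the transcription factor gene Cebpb (17.6 ± 12 against 92.2 ± 83.3 CPM, log2 difference of -2.39 ± 0.82 SE) and the collagenase gene Mmp13 (10.8 ± 3.52 against 142 ± 126 CPM, -3.71 ± 1.22). The osteocalcin gene Bglap was also among them (0.498 ± 0.13 against 39.5 ± 25.8 CPM, -6.20 ± 2.06). The myelin gene Mobp stood at 3.11 against 222 ± 374 CPM (-6.13 ± 1.83), with 2507, 19 and 25 counts in MDMA libraries 1, 2 and 3. The Wnt inhibitor gene Wif1 had 3 counts against 180, a ratio of 49.4 with a 95% counting interval of 16.7 to 242. Fkbp5 differed by -1.60 ± 0.68 on the log2 scale (SE), Ccr2 by -0.94 ± 0.99, S100a8 by -0.94 ± 1.04 and Nr4a1 by 0.07 ± 0.39. Tsc22d3 differed by -0.74 ± 0.43, H2-Ab1 by -0.59 ± 0.54 and Il1b by -1.13 ± 1.04 on the log2 scale (SE, adjusted p = 1 for each by edgeR), which leaves differences in either direction open. Since the doses are not given in the sources used here, the drugs could not be compared at matched doses.

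The serotonin and monoamine list, with 13 genes tested and no call, did not pass among stressed groups or after stress. Its camera adjusted p was 0.327 for stress, 0.561 for psilocybin, 0.754 for MDMA and 0.602 for psilocybin against MDMA. Htr1a and Taar1 had 0 counts in all libraries, which allows up to 3.8 CPM in the smallest library. The serotonin transporter gene Slc6a4 had 25, 0, 16 and 20 counts in the unstressed, vehicle, psilocybin and MDMA groups. Tph1, which encodes the tryptophan hydroxylase of peripheral and pineal serotonin synthesis, reached 508 ± 805, 1340 ± 1380, 2330 ± 2140 and 1510 ± 646 CPM (SD, n = 3). Within the vehicle group alone it ran from 6.44 to 2750 CPM.

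**Figure D4:**
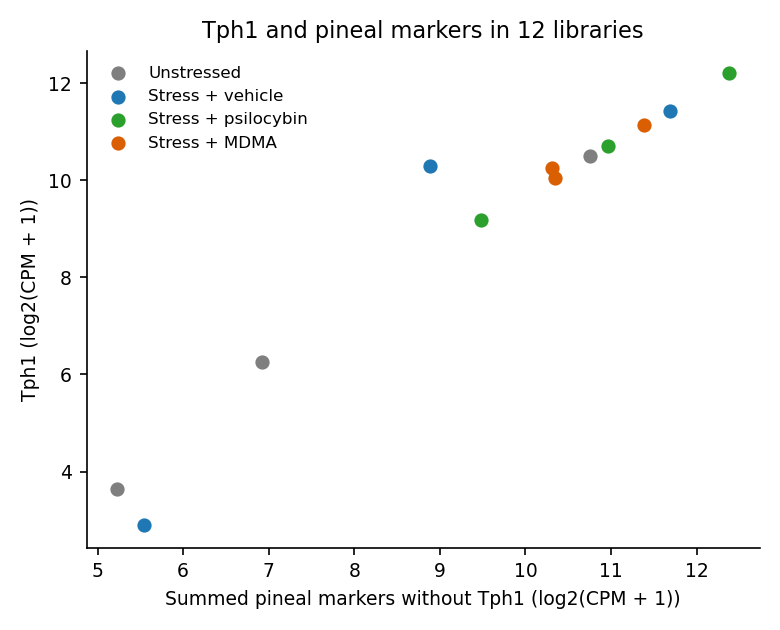
Tph1 level against the summed level of pineal markers without Tph1 in the 12 libraries, each as log2(CPM + 1); points are libraries, coloured by group. Both measures rose together across libraries (Spearman's rho of 0.944, permutation p = 4e-05), and the vehicle and unstressed libraries spread over most of the range.

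Against the unstressed group, 12 genes passed after psilocybin (4 higher and 8 lower) and 17 after MDMA (5 higher and 12 lower) by edgeR. All 8 genes lower after psilocybin were among the 12 lower after MDMA (0.00689 expected of independent lists), and 3 of the higher genes were shared (0.00143 expected). These comparisons use the same unstressed libraries and share the difference in annotation, so part of the excess may come from these. In 20 simulations of unchanged groups, each comparison had a mean of 0 calls per direction and 0 shared genes. The simulations therefore give no expected overlap for lists of this size. Genes called with one direction in all stressed groups were Klhl10, Gnas, Gid8, Ilk, Rbm42, Nufip2, Sept2 and Zc3h11a with lower and Mia2, St13 and Ormdl2 with higher counts, of which 3 (Sept2, Zc3h11a and Ormdl2) could not be counted on one side, a choice of names made after their values were seen. The neutrophil list was higher in both drug groups than in unstressed libraries. It was 2.2 above other genes after psilocybin (11 of 12 positive, camera adjusted p = 7.49e-06, adjusted p = 0.766 with an estimated correlation). After MDMA it was 3.97 above (camera adjusted p = 1.7e-15, 12 of 12 positive, adjusted p = 0.142 with an estimated correlation), and against no change fry gave it an adjusted p of 0.0231. S100a8 stood at 1.75 ± 0.16 CPM (SD, n = 3) in unstressed libraries, 108 ± 131 after psilocybin (edgeR adjusted p = 0.125) and 207 ± 223 after MDMA (adjusted p = 0.0799). The count of 12 became 4 without any one psilocybin library, and 4, 5 and 3 without unstressed library 1, 2 or 3. That of 17 became 2, 3 and 4 without MDMA library 1, 2 or 3, and 3, 4 and 3 without unstressed library 1, 2 or 3. With DESeq2 the counts were 245 and 218, and with limma voom 2738 and 1081. Fits of only the groups compared also gave more genes for each drug. No gene passed for either drug with only genes of nearly the same exons and all libraries, which are fewer genes.

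Across all 4 groups, 81 genes differed in the test of any difference with edgeR, and the count ran from 11 without unstressed library 3 to 2476 without vehicle library 2. Without vehicle library 1 or 3 it was 142 and 343, and without unstressed library 1 or 2 it was 13 each. Without psilocybin library 1, 2 or 3 it was 27, 23 and 27, and without MDMA library 1, 2 or 3 it was 29, 24 and 21. No gene passed with only genes of nearly the same exons in both annotations, which are fewer genes. Drug effects and the stress effect ran opposite ways across genes, which are not independent replicates. The Pearson correlation over 13942 genes was -0.831 for stress with psilocybin and -0.847 for stress with MDMA, where 20 simulations of unchanged groups measured against the same vehicle libraries gave -0.951 and -0.952, so that neither was stronger than shared vehicle libraries alone give. The effects of psilocybin and MDMA correlated at 0.944, against 0.951 in simulation. Observed covariances were -3.99, -4.25 and 4.31, against a simulated -4.3, -4.3 and 4.3. Of the 94 genes higher after MDMA, 86 were among the 446 lower after stress (3.01 expected of independent lists), as were both genes higher after psilocybin (0.064 expected). The simulated unchanged groups shared a mean of 400 and 395 such genes. The 3 vehicle libraries could not be split into parts of at least 2 libraries each, so part or all of this excess may come from the shared controls.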

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

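The tests of osteoblast against neutrophil markers, of annotation as a reason for the decreases after stress, of exons shared between genes and of pineal tissue were chosen only after the result was seen; the others here were written down before. What the splits of libraries would show had been entered in the wrong columns and was set right after their results were known.

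Psilocybin and MDMA libraries differed in 16 gene lists by a direct test of the difference, each drug having been set against the same vehicle libraries. The lists lower after psilocybin, in log2 difference from other genes, were neutrophil (-1.77), classical monocyte (-1.39), erythroid (-1.2), proliferation (-1.17), alternative activation (-0.992), border macrophage (-0.949), adhesion and trafficking (-0.848), microglia (-0.827), fibroblast (-0.779), mast cell and basophil (-0.74), class II antigen presentation (-0.735), inflammatory cytokine and NF-kB (-0.486), interferon-stimulated (-0.484) and glucocorticoid response (-0.399). The lists higher after psilocybin were nuclear oxidative phosphorylation (1.03) and ribosomal protein (0.434). None of these held with an estimated correlation between genes, where the smallest adjusted p was 0.126.

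The levels of cell-type lists lower after psilocybin were weighed against tissue composition. More choroid plexus in the psilocybin libraries would dilute all other cell types alike if it brought none of them. The median log2 differences were -1.77 for neutrophil, -0.57 for fibroblast, -0.46 for T and NK cell and -0.1 for endothelial and mural genes, a range of 1.68. That range rests on the neutrophil list, the largest difference of the pattern itself. Neutrophil marker sums also had an SD of 1.71 in psilocybin and 1.19 in MDMA libraries on the log2 scale, so the range cannot decide on dilution. A share of skull bone and marrow in some libraries remains open: over the 9 stressed libraries, osteoblast and neutrophil marker sums had Pearson's r of 0.727 (two-sided permutation p = 0.0225) and Spearman's rho of 0.6 (permutation p = 0.0968). Without the 2 libraries farthest from the median, r was 0.608 over 7 libraries (permutation p = 0.149). After adjustment over 3 relations the p-values were 0.0225 and 0.0968. A monocyte isolation would remove osteoblasts and neutrophils if complete. An effect of the drugs themselves on the makeup of meningeal cells stays open as untested, since tissue taken and drug given cannot be told apart in these groups.

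Genes lower in vehicle than in unstressed libraries were weighed against loss of molecules, annotation and lower transcript levels. Different gene annotation in the counting is argued against as the whole reason, because in psilocybin and MDMA libraries, counted as the vehicle libraries were, the 446 genes had a median log2 difference from unstressed of -1.02 and -0.79 against -7.47 in vehicle (-4.82 with the 260 genes at 0 in all vehicle libraries placed at their bound), a share of 0.136 (0.211 at the bound), although 7 of the 446 could not be counted in the annotation of the stressed libraries. Loss of molecules in vehicle libraries 1 and 3 remains open. Of the abundant genes, 24 were missing in both where 18.4 were expected of independent losses, a ratio of 1.3. In all 3 vehicle libraries 321 of 12292 genes were missing where 237 were expected, a ratio of 1.36. Both ratios lay under the limit set beforehand. Still, more genes were missing in all 3 than independent losses give, and 135 of the 321 were among the genes called lower. Independent losses are therefore not shown to account for all of them. Levels low in all vehicle libraries alike are argued against for the genes called lower without vehicle library 2, taken as a set. Over the 3131 of these 3192 genes also tested with all libraries, the median log2 ratio of library 2 to unstressed was -0.62, against -0.26 for all genes, a difference of -0.37. These genes were chosen on vehicle libraries 1 and 3, so a smaller set low in all 3 libraries is left open. Lower transcript levels in stressed mice stay open for the 446 genes, whose median log2 ratio in vehicle library 2 was -4.46, because the genes had been chosen on that library too.

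Genes different between unstressed and every stressed group were weighed against annotation. None of the 11 had nearly the same exons in both annotations, a ratio of 0 to the 17.4% of all tested genes, which is consistent with different gene annotation in the counting as a reason. Exons shared with another gene or much longer exons in one annotation were seen in 10 of the 11, each over 2 times longer in the annotation with the higher counts, against 17.1% of tested genes in either direction (Fisher's exact p = 1.96e-07). Restraint stress stays open, since 0 of the 11 had comparable exons where 1.91 were expected, with a chance of none of 0.122.

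The splits of 6 libraries into 3 and 3 are too few for a share under 0.05. Only 1 of the 10 splits, the real one, gave as many genes as the 477 after stress (highest other 42), and the same 1 of 10 held for the 2 genes after psilocybin (highest other 0), the 94 after MDMA (0), the 12 for psilocybin against unstressed (0) and the 17 for MDMA against unstressed (0). The libraries of psilocybin and vehicle were taken as paired by number only after the fits, and the labels name no such pairing. With that pairing, the real split is among 4 that part all 3 pairs (highest other 0), while the other 6 part only 1 pair (highest 0). For psilocybin against MDMA, all 10 splits gave 0 genes by edgeR, where 81 genes had an unadjusted p under 0.05 and DESeq2 and limma voom called 0 and 1. For any difference among the 4 groups, 1 of 100 splits, the real one, gave as many as 81 genes (highest other 32). In 20 simulations of unchanged groups whose vehicle libraries kept their own spread, at most 6 passed (mean 0.95). The real division thus gave more genes than any other drawn. However, random divisions mostly scatter the vehicle libraries, which have the larger spread, over several groups. The simulations kept them together but overstated the calls of each drug against vehicle, so neither settles the source of this count. The unstressed libraries were counted with another annotation, which neither the splits nor the simulations set apart. The count therefore cannot be assigned to stress or drugs. Of the drawn splits, 54 part all 3 pairs of vehicle and psilocybin, with the same highest other of 32. With the replicate number as a block the count was 16.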

How the results depend on the processing

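The fits limited to genes of nearly the same exons or to the 9 stressed libraries and the fit without vehicle libraries 1 and 3 together were chosen after seeing the data; the others were planned. Counts are for stress against unstressed (477), psilocybin against vehicle (2), MDMA against vehicle (94), psilocybin and MDMA against unstressed (12 and 17) and any difference (81), in that order where several follow; the cause was not tested for changes under any of these settings. No result past its threshold reversed its direction. Of the log2 fold changes of named genes under an alternative, 78 had the opposite sign or 0, none of them past the threshold in either fit. With the median of the list in place of the sum, 26 of 52 differences in marker level moved by more than 1 SD and 17 changed sign. Among these, neutrophil markers in vehicle against unstressed libraries went from 1.51 to -0.398, border macrophage markers from 0.638 to -1.99, and classical monocyte markers in psilocybin against vehicle from -0.39 to 0.915. Leaving out each library in turn gave 27 of 312 marker differences the other sign. All 312 stayed within 1 SD, but with 3 libraries per group no larger shift is possible, so this was no test. With DESeq2's size factors in edgeR the first 3 counts were 298, 0 and 3. With no filter they were 291 and 7 for the first 2, then 51, 65 and 276 for the drugs against unstressed and any difference. The DESeq2 test gave 1746, 1061, 1336, 245, 218 and 1423, and limma voom gave 1, 0, 0, 2738, 1081 and 1727, with 1 gene for psilocybin against MDMA. With only the 2 groups compared the counts were 2, 0, 0, 1377 and 235. Thinning to the smallest library gave 164, 1 and 3, then 11 for MDMA against unstressed and 45 for any difference, with 13 for psilocybin against unstressed. Leaving out mitochondrial, haemoglobin and immunoglobulin genes gave 47 for MDMA against vehicle, and the filter of 5 CPM left every count within 1.5 times its value.

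Only genes with nearly the same exons, which are fewer genes, gave 37 for stress, 16 for MDMA against vehicle and 0 for each drug against unstressed and for any difference, and with only the 2 groups compared as well 0 for stress, 45 for psilocybin and 5 for MDMA against unstressed. The 9 stressed libraries alone gave 0 for each drug against vehicle, and leaving out vehicle libraries 1 and 3 together also gave 0 for each, then 747, 412 and 569, with the lone vehicle library assumed to vary like the other groups. The last setting kept 107 of the 477 genes, against 470 with DESeq2 and 297 with its size factors. Leaving out each library in turn gave 8 to 3665 genes for stress, 0 to 3533 for psilocybin, 0 to 3612 for MDMA, 0 to 0 for psilocybin against MDMA, 3 to 5 and 2 to 4 for the drugs against unstressed and 11 to 2476 for any difference. Correlations of effects across genes then ran from -0.9211 to -0.717 for stress with psilocybin, from -0.9259 to -0.7432 for stress with MDMA and from 0.9055 to 0.9744 for both drugs, and with a prior count of 5 they were -0.7165, -0.7579 and 0.8836. The replicate number as a block gave 10, 0, 0, 5, 5 and 16 genes. For psilocybin against vehicle, where the numbers were taken to pair the libraries, the block changed no call but those of the 2 genes. In the other 5 pairs of groups not every correlation of deviations was over 0.1 (7 of 18 in all, from -0.109 to 0.318). As a hint from the data, 9 of the 12 libraries correlated best with a library of their own number. Of the 16 lists that differed between psilocybin and MDMA, 16 passed under DESeq2's size factors, both filters, the block and without vehicle libraries 1 and 3, 15 with only the 2 groups and 0 with an estimated correlation or fry. Among other values, 1512 log2 fold changes of named genes under an alternative kept their direction and side of the threshold, 346 fell short of it and 32 came to pass it. The series table held the same counts as the sample files and gave no other value. At 807725 to 5136953 counts per library, genes near 3.8 CPM could not be measured in the smallest library.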

Other observations

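The test of Tph1 against pineal markers and the fits limited to genes with nearly the same exons were chosen only after the result was seen; the lists of pineal, leukocyte and osteoblast markers were also written after the first look at the data.

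With only genes of nearly the same exons in both annotations and only the libraries compared, 45 genes passed for psilocybin and 5 for MDMA against unstressed. After MDMA, the neutrophil granule gene Ngp rose by 4.88 ± 0.56 (SE) on the log2 scale, from 106 ± 45.2 to 3360 ± 1650 CPM of these genes (SD, n = 3, edgeR Benjamini-Hochberg adjusted p = 0.0108), with 326 ± 259 CPM in vehicle libraries. Chil3, a chitinase-like gene of neutrophil precursors and alternatively activated macrophages, rose by 5.11 ± 0.64 to 1380 ± 893 CPM (adjusted p = 0.0108), and S100a9, a calprotectin subunit, by 7.11 ± 0.89 to 527 ± 502 CPM (adjusted p = 0.0108). Chil3 stood at 36.9 ± 13 CPM in unstressed and 319 ± 199 in vehicle libraries, and S100a9 at 3.27 ± 1.78 and 55.9 ± 7.19. Part of each difference from unstressed was thus present in vehicle libraries, without MDMA. Lbh, a transcription cofactor of neural crest derivatives, fell by 3.35 ± 0.44 after MDMA (adjusted p = 0.0117) and by 3.5 ± 0.32 after psilocybin (adjusted p = 0.00781), from 1450 ± 168 CPM in unstressed libraries, but stood at 1490 ± 2350 CPM in vehicle libraries. The cytokine receptor gene Lifr fell by 2.67 ± 0.38 after MDMA (adjusted p = 0.0185) and by 2.01 ± 0.30 after psilocybin (adjusted p = 0.0363). Lifr stood at 6830 ± 1730 CPM in unstressed and 2900 ± 2240 CPM in vehicle libraries. These 5 genes were all that passed for MDMA.

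Of the 45 genes for psilocybin, 12 were higher and 33 lower. Ttr rose by 3.19 ± 0.43 on the log2 scale, from 21800 ± 3350 to 208000 ± 88500 CPM of these genes (n = 3, edgeR adjusted p = 0.0271). Choroid plexus markers stood at 87400 ± 31200 CPM against 32600 ± 14300 in unstressed libraries, but that sum includes Ttr itself and is no separate evidence. S100a9 rose by 5.70 ± 0.95 (adjusted p = 0.0363), the endothelial fenestra gene Plvap by 1.88 ± 0.33 (adjusted p = 0.0405) and the glutathione transferase gene Gstm1 by 2.58 ± 0.43 (adjusted p = 0.0363). Vehicle libraries held 117000 ± 114000 CPM of Ttr, 55.9 ± 7.19 of S100a9, 754 ± 748 of Plvap and 404 ± 254 of Gstm1. In unstressed libraries S100a9, Plvap and Gstm1 stood at 3.27 ± 1.78, 372 ± 110 and 142 ± 77.4 CPM. The transcription factor gene Zic1 fell by 1.60 ± 0.25 (adjusted p = 0.0363), the imprinted transcript H19 by 2.15 ± 0.38 (adjusted p = 0.0417), and the collagen gene Col5a1 by 1.97 ± 0.40 (adjusted p = 0.0496). Zic1, H19 and Col5a1 stood at 450 ± 176, 1330 ± 2040 and 8.32 ± 10.3 CPM in vehicle libraries. Their unstressed levels were 875 ± 29.4, 1780 ± 535 and 152 ± 39.3 CPM. These names were chosen after their values were seen. With the same genes but all 12 libraries in the fit, 0 genes passed for either drug, so that every call named here was lost, and over all genes and libraries the counts were 12 and 17.

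Tph1 varied between libraries of one group more than between groups, and pineal tissue carried along with some of the meninges is a candidate explanation. Over 12 libraries, Tph1 followed the summed pineal markers without Tph1 with Spearman's rho of 0.944 (permutation p = 4e-05) and Pearson's r of 0.97 (permutation p = 1e-05, the smallest that the permutations can give), or 0.00012 and 3e-05 after adjustment over 3 relations. Without the 2 libraries farthest from the median, r was 0.939 (p = 0.0002), and over the 9 stressed libraries r was 0.948 (exact permutation p = 0.000311). Pineal markers summed to 1130 ± 1760, 2610 ± 3100, 5000 ± 4520 and 3250 ± 1440 CPM (SD, n = 3) in the unstressed, vehicle, psilocybin and MDMA groups. A monocyte isolation would remove pinealocytes if complete, and no biological explanation of the Tph1 level was tested.

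Markers of other cells were measured in every group. The leukocyte list summed to 537 ± 111, 608 ± 184, 566 ± 460 and 1240 ± 399 CPM (SD, n = 3) in the unstressed, vehicle, psilocybin and MDMA groups, and T and NK cell markers to 162 ± 126, 217 ± 128, 88.4 ± 46.9 and 133 ± 42.9. Neural and glial markers without Ttr summed to 1040 ± 524, 1370 ± 668, 1640 ± 654 and 2690 ± 1840 CPM, and erythroid markers to 38.4 ± 6.09, 40 ± 43.3, 123 ± 122 and 206 ± 108.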
